A study of Drosophila melanogaster with 22 samples.

How the data were processed

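RNA of Drosophila melanogaster was measured on 11 two-colour Agilent arrays, 22 labelled samples in all. The flies were kept on cornmeal food, total RNA was extracted with Trizol and Qiagen reagents and labelled with a two-colour Quick Amp kit, per the labels. The groups, replicate numbers and dyes were taken from the labels: Zeus RNAi in reproductive organ with 3 biological arrays (RNAi in Cy3) and 1 technical array (RNAi in Cy5), Zeus RNAi in whole body with 3 arrays (RNAi in Cy5), and Caf40 RNAi in white prepupae with 2 arrays of each orientation. Every RNAi sample shared its array with a wildtype sample. Which reproductive organ replicate the technical array repeats is not given in the sources used here. The submitters' design text speaks of males for whole body and reproductive organ and does not mention the prepupae, whose sex is not given. The labels call the other samples biological replicates without saying how they were raised, so p-values measure the spread between these samples, pooled over the 3 comparisons.

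The deposited scanner files hold spot intensity values on a linear scale, mean and background signals of the green and red channels, made with Agilent Feature Extraction per the submitters' processing notes and, per the file headers, with version 10.5.1.1 for slides 1 and 2 (scan 1) and 10.7.3.1 for slides 3 and 4 (scan 2). Slide 1 held reproductive organ replicate 1 and the 3 whole body arrays, slide 2 reproductive organ replicates 2 and 3, slide 3 prepupae replicates 2 and 4, and slide 4 prepupae replicates 1 and 3 and the technical array. Each array had 45020 spots, of which 43603 were gene spots of 32162 probes. The authors' value table holds log2 values, a scale found by setting its 22 columns against the scanner values of each channel; how it was normalized is not given in the sources used here. Of its columns, 6 followed their own channel best, 14 another array of their own group and 2 a channel of the other genotype, with a lowest best correlation of 0.955. The labels of reproductive organ replicates 2 and 3 and of whole body replicates 1 and 3 are exchanged in it. No prepupae pair of columns follows the array of its own label. The pairs of replicates 1, 3 and 4 follow the arrays of replicates 2, 1 and 3, that of replicate 3 with the dyes turned. The pair of prepupae replicate 2 follows the array of replicate 4 with the genotypes turned. The value table was therefore used only as an alternative, and its centring stays unknown.

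The medians of its columns, in the order of the RNAi and wildtype columns of each replicate, were 8.51 and 8.55, 8.59 and 8.58, 8.56 and 8.76, and 8.63 and 8.58 in prepupae. They were 8.61 and 8.58, 8.61 and 8.58, and 8.62 and 8.59 in whole body. They were 8.07 and 8.06, 8.08 and 8.11, 8.07 and 8.07, and 8.12 and 8.08 in reproductive organ.

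Signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50, mean signal and median background), and the log2 ratio of red over green was normalized within each array by loess. Control spots and spots with an outlier mark (164 to 298 per array) had weight 0 in loess and were left out afterwards. No spot was saturated. Spots of one probe were averaged, and then probes of one gene. Probe names were brought to current symbols through a table of gene names that gives locus tags, accessions and synonyms. Of the 32162 probes, 20712 matched, 18874 by locus tag, 676 by accession, 826 by synonym and 336 by symbol, and gave 13185 genes. The 11450 probes without a match were left out. Coordinates are those of the files, in the dm3 build, and whether a probe lies in an exon was not analysed here.

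All 10 biological arrays entered 1 limma fit (lmFit, eBayes) with a coefficient for each of the 3 comparisons, each array's ratio signed by its dye orientation, and a gene-specific dye term that is common to all arrays and estimable from the dye-balanced prepupae arrays. The technical array was left out of this fit. Each gene had 1 spread for all 3 comparisons, so a standard error need not match the spread of the n arrays beside it. For Caf40 the uncorrected ratios had an SD of 0.51 in prepupae, 0.15 in reproductive organ and 0.023 in whole body. A gene was tested in a comparison when at least 1 of its probes was well above background on every biological array, in the channel of the RNAi group or in that of the wildtype group, and a probe counted as such when at least 0.5 of its spots were. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. The difference between reproductive organ and whole body, and that between Zeus RNAi in reproductive organ and Caf40 RNAi in prepupae, were contrasts in the same fit. The fit without the dye term, an alternative set in advance, is printed beside gene counts and many gene and list values of the Zeus comparisons because of the check with the technical array. That check, the fit of the Zeus arrays with a dye term of their own and the simulations of dye terms present on the prepupae arrays alone or on all arrays were chosen after the data were seen. In the simulated check with the technical array, reproductive organ effects were the mean of its 2 dye orientations, every array had noise of its own, and the estimated dye terms were scaled so that simulated estimates had the measured SD.

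A gene that was well above background on no biological array of 1 group, and on at least 1 of the other, is given as "at least" a fold, the mean log2 signal of the bright group over that of the dim group. In the dim group each array contributed the higher of the gene's own signal and the lowest signal among gene spots well above background on that array and channel, after loess and Aquantile normalization. These folds are open to dye bias where dyes were not balanced.

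Sets of genes were tested with camera at a preset inter-gene correlation of 0.01, with 40 lists per comparison having at least 3 tested members, and Benjamini-Hochberg adjustment over all lists and comparisons. The 42 lists cover pathways, complexes and markers of tissues and cell types. They called 32 results, 11 in reproductive organ, 13 in whole body and 8 in prepupae, none of which passed with an estimated correlation. The fry test, which asks whether a set's genes move one way on balance and does not compare them with other genes, called 10, 2 and 14. In some lists, none of them called, the median, the mean and the test differed in sign. List members were found by symbol, 13 by CG number, and 3 had no match. The X chromosome was compared with Fisher's exact test, two-sided. Correlations and overlaps between comparisons were set against 50 simulated data sets without changed genes and against independent lists.

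Named genes followed a rule: Zeus and Caf40 in every comparison; the 12 highest and 12 lowest log2 ratios of each comparison, and 6 and 6 of each difference, among genes past the threshold whose dye-corrected ratio had 1 sign on every array; and, of each list, up to 4 members past the threshold with the lowest adjusted p. The design, the lists, this rule and most alternatives were fixed before the data were examined. The joint fit and the gene list test were tried on simulated ratios, which does not cover background correction, loess, probe averaging or the filter on dim probes. With 200 changed genes per comparison among 13185 fitted and a dye term common to all arrays, log2 changes of 0.5, 1 and 2 were recovered in 5.97%, 50.7% and 89.4% of cases in reproductive organ, 2.99%, 43.3% and 95.5% in whole body and 26.9%, 95.5% and 93.9% in prepupae. False calls were 3%, 6% and 5.88% of all calls. These figures do not cover a dye term that differs between arrays, nor a spread that does. All simulations here drew noise with 1 spread per gene on every array. The measured ratios, real changes included, had SDs across genes of 0.43 to 0.63 on the biological Zeus arrays and 0.65 to 1.22 on the prepupae arrays. Recovery and false calls need not hold at such unequal spreads.

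Alternatives changed 1 choice at a time except where 2 are named: the dye term, the technical array, a separate fit for each comparison (which for the Zeus comparisons also takes out the dye term, since their dyes were not balanced), Agilent's processed signals, no background correction, median centring, scaling between arrays, the filter on dim probes, the brightest probe, slide as a random block, array weights, separate channels, the authors' value table, other thresholds, an intensity trend and each array left out. The pairing of the 2 samples on an array is part of the ratio. Their deviations from the group means correlated between -0.156 and 0.54 over 7795 genes, above 0.1 for 6 of the 10 arrays.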

Results

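The data came from 11 two-colour oligonucleotide arrays of Drosophila melanogaster, each hybridised with RNA of an RNAi sample in one dye and of a wildtype sample in the other, which gave 22 labelled samples. Zeus, listed today as Rcd-1r (CG9573), is a young autosomal gene derived from Caf40, listed as Rcd-1 (CG14213), an X-linked gene that encodes a subunit of the CCR4-NOT deadenylase complex. Zeus RNAi was compared with wildtype in male reproductive organ (3 biological arrays and 1 technical array with the dyes turned) and in male whole body (3 arrays). Caf40 RNAi was compared with wildtype in white prepupae (4 arrays). On the prepupae arrays 32.8% to 58.2% of gene spots in the green channel (Cy3) were well above background, against 63.9% to 75.9% on the other arrays, and no spot was saturated. In the red channel (Cy5) the share lay between 61.8% and 77%. Median green signals, background included, were 410, 314, 124 and 187 on prepupae replicates 1 to 4, against 159 to 264 on the other arrays. The low share of green spots thus did not go with a low median signal on every prepupae array. The number of arrays, 3 or 4 in a comparison, limits the precision of every value that follows.

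Zeus was lower in the Zeus RNAi samples of both sample types, which is the check of the labels. In reproductive organ its log2 ratio of RNAi over wildtype was -2.22 ± 0.27 (standard error, n = 3, adjusted p = 0.00218), and -1.69 ± 0.28 without a dye term (adjusted p = 0.0059). In whole body it was -1.37 ± 0.27 (n = 3, adjusted p = 0.022), and -1.90 ± 0.28 without a dye term (adjusted p = 0.00617). Caf40 fell in prepupae under its own RNAi, to a log2 ratio of -1.39 ± 0.17 (n = 4, adjusted p = 0.000406), and was lower on 4 of 4 arrays. Under Zeus RNAi, Caf40 was at -0.84 ± 0.26 in reproductive organ (adjusted p = 0.0454) and at -0.85 ± 0.26 in whole body (adjusted p = 0.0695), and both values passed without a dye term (adjusted p = 0.0283 and 0.0296). The Zeus call in whole body was lost without whole body replicate 1, 2 or 3 (-1.29, -1.44 and -1.37), and the Caf40 call in reproductive organ was lost without any 1 array (-0.93 to -0.78) except prepupae replicate 3 or 4 (-0.54 and -1.15). Caf40 in whole body passed without prepupae replicate 3 or 4 (-1.16 and -0.55). Zeus was not tested in prepupae, where it was well above background in 1 RNAi sample and 3 wildtype samples of 4, and its log2 ratio there was -0.42.

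The arrays carried 1 Zeus probe, at positions 9012924 to 9012983 of 2L in the dm3 build, with 2 spots. Caf40 had 2 probes, which disagreed. The probe at X, 19534725 to 19534784, gave mean log2 ratios of -1.35, -1.55 and -2.63 in reproductive organ, whole body and prepupae, and the probe at X, 19533113 to 19533172, gave -0.23, -0.26 and -0.15. The Caf40 values above average both probes. Whether the Caf40 probes bind Zeus RNA or the RNAi construct was not tested.

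**Figure D1:**
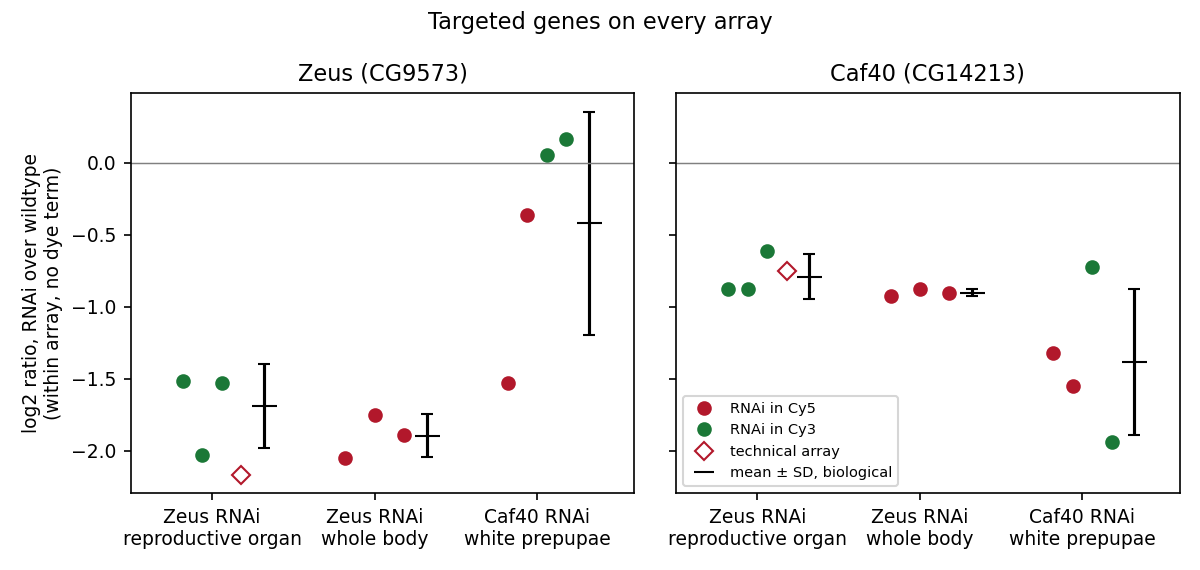
Log2 ratio of RNAi over wildtype on each array for Zeus and Caf40, before any dye term, with red points for RNAi in Cy5, green points for RNAi in Cy3, an open diamond for the technical array and bars for the mean and SD of the biological arrays. Zeus lay between -2.05 and -1.52 on the 6 biological Zeus RNAi arrays and at -2.17 on the technical array, and Caf40 lay between -1.94 and -0.73 on the 4 prepupae arrays.

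All 3 biological reproductive organ arrays had the RNAi sample in Cy3 and all 3 whole body arrays had it in Cy5, so a gene-specific dye term was estimated from the prepupae arrays, which held 2 of each orientation. The technical array allowed a check of this term on Zeus RNA. The term enters the reproductive organ mean and the technical array with opposite sign, so noise in it alone lowers their correlation. The check was therefore simulated, in 50 data sets each, with a dye term on all arrays and with one on the prepupae arrays only. Across 11348 genes the mean and the technical array correlated at r = 0.794 before the dye term and at 0.0521 after it (genes are not replicates). The simulated correlation went from a mean of 0.131 to 0.587 (0.562 to 0.616) for a term on all arrays, and from 0.743 to 0.0604 (0.0401 to 0.0836) for one on the prepupae arrays only. The dye effect within reproductive organ was taken from other arrays than the prepupae term. It correlated with that term at r = 0.0886 over 7803 genes, with SDs of 0.18 and 0.51. The technical array shared slide 4 and the scan with prepupae replicates 1 and 3, while the biological arrays lay on slides 1 and 2 of the other scan. Errors shared within a slide or scan can enter this correlation, and the simulations, with independent noise on every array, do not hold them. Simulations gave 0.834 to 0.862 for a term on all arrays and -0.0367 to 0.0453 for one on the prepupae arrays only. The measured value lay above the second range and below the first. With prepupae dye terms placed on the prepupae arrays alone and no changed gene, 50 simulated data sets gave a mean of 1110 called genes in reproductive organ, 1140 in whole body and 0 in prepupae. The terms were not scaled for their own noise in these data sets, so the counts can run high. Because of this check, gene counts and many gene and list values of the Zeus comparisons are given with the dye term, the design fixed in advance, and without it. Below, a Zeus log2 ratio given once comes from the fit with the term, unless another fit or uncorrected ratios are named.

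**Figure D2:**
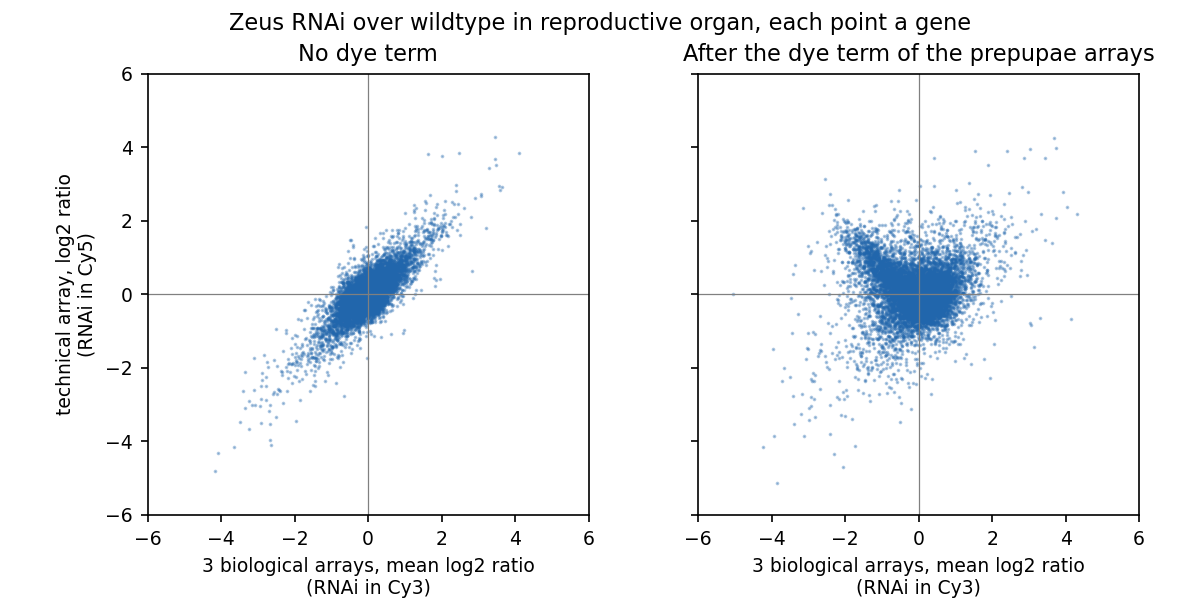
Log2 ratio of RNAi over wildtype of each gene in reproductive organ, before (left) and after (right) the prepupae dye term. One axis is the mean of the 3 biological arrays and the other the technical dye-turned array. The correlation across genes was 0.794 before and 0.0521 after the term. Simulations gave 0.562 to 0.616 after a term present on all arrays and 0.0401 to 0.0836 after one on the prepupae arrays only.

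Under Zeus RNAi in reproductive organ, BaraA2, the precursor of an immune-induced peptide family, rose to a log2 ratio of 3.92 ± 0.47 (standard error, n = 3, adjusted p = 0.00218; 3.28 without the dye term), and BomS4, a Bomanin peptide gene of the Toll response, to 3.63 ± 0.64. PH4alphaSG1, a prolyl hydroxylase subunit, rose to 4.04 ± 0.31 (3.58 without the dye term), and Marf, which encodes mitofusin, to 3.18 ± 0.49. CG34331 was at least 9.75-fold higher and the eggshell gene Cp7Fb at least 7.15-fold higher, since their wildtype samples were not well above background. Cyp12d1-d, a cytochrome P450 gene linked to insecticide response, fell to -3.85 ± 0.33 (-4.17 without the dye term), CG18404 to -4.24 ± 0.19 (-4.07), the trypsin gene Try29F to -3.51 ± 0.42 and the small GTPase gene RabX2 to -3.70 ± 0.34. The photolyase gene phr6-4 was at least 8.52-fold lower and CG11893 at least 6.78-fold lower.

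Of 11350 genes tested in reproductive organ, 1301 were higher and 1508 lower under Zeus RNAi with the dye term, and 778 were higher and 620 lower without it. Both fits called 614 genes higher and 428 lower, and none in opposite directions, while 129 of the 2809 genes turned sign without the term. CG4998 (-5.05 ± 1.03 with the dye term), lncRNA:CR32661 (-3.48 ± 0.33) and the cuticle protein gene Cpr65Ec (at least 3.23-fold lower) passed in the first of these 2 fits and not in the second. The first 2 genes stood at -2.89 and -1.98 without the term. The technical array, which correlated across genes at r = 0.685, 0.907 and 0.508 with replicates 1 to 3 and can repeat RNA of one of them, showed the same direction for 752 of the 778 higher and 596 of the 620 lower genes called without the term. With the term the counts were 1207 of 1301 and 1251 of 1508. Within slide 2, which is the same fit as without replicate 1, the count was 1137. Slide 1 held 1 reproductive organ array, which was assumed to vary like those of the other comparisons, so no count is given for it. Without replicate 2 the count was 1785, and slide as a random block gave 1650.

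Accessory gland genes were the group with the most members lower in reproductive organ. Of 46 tested, 29 fell and 17 did not pass, and 34 fell and 1 rose when adjusted over the list alone. Sex peptide (SP), which alters female behaviour after mating, fell to -1.72 ± 0.13 (-1.60 without the dye term), Acp98AB to -2.68 (-2.23), Acp53Ea to -1.76 (-1.59) and the serpin gene Spn53F to -1.55 (-1.50). The list's median was -0.91, with adjusted p = 5.5e-11 by camera and adjusted p = 0.896 with an estimated correlation. Without the dye term the median was -0.75 with 26 lower members, and the uncorrected median was -0.64 on the array of slide 1, -0.92 and -0.74 on those of slide 2 and -0.86 on the technical array.

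Odorant-binding protein genes fell in 10 of 35 cases in reproductive organ (25 did not pass; 10 adjusted over the list alone), with Obp22a at -1.38 and Obp8a at -1.25. Their camera adjusted p was 0.00335, the adjusted p = 0.896 with an estimated correlation, and the median moved from -0.42 to -0.28 without the dye term. Antimicrobial and induced immune peptide genes rose in 4 of 23 cases (2 adjusted over the list alone), led by BaraA2 and by PGRP-SD, which senses bacterial cell walls, at 2.20 ± 0.31. Their median was 1.87 (camera adjusted p = 0.00322; adjusted p = 0.896 with an estimated correlation) and 1.18 without the dye term (adjusted p = 0.0241), and the uncorrected medians were 1.75 on slide 1 and 0.73 and 0.18 on slide 2. Meiotic arrest genes, testis-specific transcription factors needed for spermatid gene expression, fell in 6 of 12 cases (9 adjusted over the list alone), with nht at -1.03 and tomb at -0.66. Their median of -0.61 (camera adjusted p = 0.000453; adjusted p = 0.896 with an estimated correlation) became -0.27 without the dye term (adjusted p = 0.0458), where 2 members fell, nht stood at -0.42 (adjusted p = 0.347) and tomb at -0.28 (adjusted p = 0.369).

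Late spermatocyte and spermatid genes depended on the dye term. With it, 25 of 42 were lower in reproductive organ (30 adjusted over the list alone; median -1.32, camera adjusted p = 5.5e-11, adjusted p = 0.896 with an estimated correlation), and without it 1 was lower (median -0.09, adjusted p = 0.547). The list's uncorrected medians were -0.28 on slide 1, -0.07 and 0.12 on slide 2 and -0.10 on the technical array. Thus neither dye orientation of these arrays showed a fall of the size found with the term. On the prepupae arrays, which give the term, medians were -0.66 and -1.86 with RNAi in Cy5 and 0.84 and 1.95 with RNAi in Cy3. The sperm tail gene Mst98Cb was at -2.21 and -0.21 in the 2 fits, and the testis gene ocn at -2.39 and -0.70. The postmeiotically transcribed gene p-cup was lower in both, by at least 7.15-fold. Midgut digestive enzyme genes showed the opposite dependence, with 2 higher and 6 lower of 38 and no call with the term (median -0.59, adjusted p = 0.162), and 2 higher and 8 lower with a call without it (median -0.99, adjusted p = 1.27e-05; adjusted p = 0.958 with an estimated correlation). Among them thetaTry, a trypsin gene, fell to -3.19 ± 0.24 with the term and to -3.36 without it. Muscle structural genes were higher in 0 and lower in 2 of 25 cases with the term and not called (median -0.29, adjusted p = 0.377). Without it 2 were higher and the list was called higher (median 0.59, adjusted p = 0.0241; adjusted p = 0.995 with an estimated correlation). Its uncorrected medians were 0.36 on slide 1, 0.48 and 0.79 on slide 2 and 0.34 on the technical array. Genes of the somatic cells of the testis rose in 3 of 10 cases with the term (3 adjusted over the list alone; median 0.38, camera adjusted p = 0.0334, adjusted p = 0.896 with an estimated correlation), and were not called without it (median 0.12, adjusted p = 0.166). The other lists called in 1 fit only moved in the same direction in both. Cuticle protein genes (3 higher and 14 lower of 51, the same counts adjusted over the list alone; camera adjusted p = 0.00145) went from a median of -0.72 to -0.12 without the term, and testis-specific proteasome genes (6 lower of 12, 6 adjusted over the list alone; 0.00145) from -0.78 to -0.11. Homeotic and wing patterning genes (5 higher of 14, 7 adjusted over the list alone; 0.0415) went from 0.35 to 0.15 (adjusted p = 0.896 with an estimated correlation for each of these 3). Cytosolic ribosomal protein genes (10 higher and 5 lower of 94, 8 and 4 adjusted over the list alone; 0.0172) went from 0.25 to 0.08 (adjusted p = 0.963 with an estimated correlation). Chitin genes were called higher without the term alone (median 0.33, adjusted p = 0.00772; adjusted p = 0.958 with an estimated correlation), and stood at 0.54 with it, with 4 higher of 20 (6 higher and 1 lower adjusted over the list alone). In all, 5 lists were higher and 6 lower of 40 tested in reproductive organ with the dye term, 7 were called without it and 4 by both in the same direction.

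Under Zeus RNAi in whole body, CG16826 fell to a log2 ratio of -7.66 ± 0.32 (standard error, n = 3, adjusted p = 5.3e-05; -7.67 without the dye term). The larval storage protein gene Lsp2 fell to -4.79 ± 0.58 (-4.36), Tep2, which encodes a thioester protein of the immune response, to -4.44 ± 0.38 (-3.93), Cyp12d1-d to -4.30 ± 0.33 (-3.98) and Desat2, a fatty acid desaturase gene, to -3.95 ± 0.33 (-3.89). The serine protease gene spirit, which acts upstream of Toll, was at least 16.2-fold lower, and the acyl-CoA oxidase gene Acox3 at least 22.1-fold lower. BomBc3, a Bomanin gene, rose to 3.20 ± 0.23 (3.27 without the dye term), ninaA, a chaperone of rhodopsin, to 3.04 ± 0.15 (2.82) and the cuticle protein gene Cpr72Ec to 6.38 ± 0.53 (4.51), and CG34331 was at least 24.3-fold higher.

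Of 12008 genes tested in whole body, 712 were higher and 547 lower with the dye term, and 219 were higher and 353 lower without it. Both fits called 129 higher and 259 lower, and 90 of the 1259 genes turned sign without the term. The 12 lowest genes passed in both fits. Of the 12 highest, CG8517, Cpr50Ca, Osi6, CG31626, Osi2, fon and Cpr66Cb passed in the first of these 2 fits and not in the second. Without the term CG31626 moved from 2.96 to 0.18 and Cpr66Cb from 2.80 to 0.12. All 3 arrays lay on slide 1, the count without whole body replicate 1, 2 or 3 was 120, 132 or 208, without reproductive organ replicate 1 or 2 it was 814 or 717, and without prepupae replicate 3 it was 3401. Slide as a random block gave 177.

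Midgut digestive enzyme genes fell in whole body in 7 of 39 cases (32 did not pass; 9 adjusted over the list alone), with the trypsin genes gammaTry at -4.05, thetaTry at -2.52 and deltaTry at -2.27 and the maltase gene Mal-A3 at -1.75. Their median was -1.31 (camera adjusted p = 1.01e-07; adjusted p = 0.896 with an estimated correlation) and -0.92 without the dye term, with uncorrected medians of -0.80, -0.67 and -0.90 on the 3 arrays. Accessory gland genes were higher in 2 and lower in 7 of 46 cases (2 and 9 adjusted over the list alone; median -0.37, camera adjusted p = 0.0152, adjusted p = 0.896 with an estimated correlation), and the median was 0.01 with median centring in place of loess. Among them Spn53F was at -0.91 and Acp53C14c at -1.76, while CG31704 was at 0.74 and Obp56i at 1.06, and CG31704 moved to -0.04 without the dye term. Of the Turandot stress genes 1 of 4 fell (3 adjusted over the list alone), TotX at -2.31 ± 0.46 (median -1.86, camera adjusted p = 0.0338; adjusted p = 0.896 with an estimated correlation). General proteasome subunit genes had a median of -0.19 in both fits with 0 of 32 members past the threshold in the limma test (camera adjusted p = 0.0364; adjusted p = 0.896 with an estimated correlation).

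Spermatid genes again moved with the dye term, here upwards. Of 42, 19 were higher and 1 lower with the term (35 and 1 adjusted over the list alone; median 1.44, camera adjusted p = 2.84e-13, adjusted p = 0.896 with an estimated correlation), and 1 was higher and 1 lower without it (median 0.11, adjusted p = 0.645). The sperm genes dj and Mst84Dd were at 2.29 and 2.12 with the term and at 0.48 and 0.40 without it, while p-cup was at least 4.49-fold lower and passed in both fits. Muscle structural genes went from a median of 0.77 to -0.06, cuticle protein genes from 0.80 to -0.09 and meiotic arrest genes from 0.33 to -0.09 without the term, and none of these lists was then called (adjusted p = 0.896 with an estimated correlation for each with the term). Antimicrobial genes were called only without the term, with 3 higher and 1 lower of 26 (median 1.43, adjusted p = 0.000179; adjusted p = 0.958 with an estimated correlation). Their uncorrected medians on the 3 arrays were 2.73, 0.40 and 0.79. In all, 8 lists were higher and 5 lower of 40 tested with the term, 8 were called without it and 4 by both in the same direction.

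Under Caf40 RNAi in white prepupae, Hsp70Bb rose to a log2 ratio of 5.90 ± 0.80 (standard error, n = 4, adjusted p = 0.000689), Hsp68 to 4.90 ± 0.26, Hsp22 to 4.82 ± 0.56 and Hsp26 to 3.63 ± 0.19. The near-identical Hsp70 genes can share signal on their probes. The Bomanin genes BomS2 and BomS3 rose to 5.42 ± 0.41 and 5.31 ± 0.39, and BaraA2 to 4.33 ± 0.31. Act88F, the flight muscle actin gene, fell to -5.56 ± 0.30, and fln, which encodes the flight muscle protein flightin, was at least 30.8-fold lower. ImpE2, an ecdysone-inducible gene, fell to -5.08 ± 0.45, the drosomycin-like gene Drsl6 to -5.94 ± 0.35, Osi18 to -4.86 ± 0.35 and CG7924 to -6.28 ± 0.25.

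Of 8020 genes tested in prepupae, 1614 were higher and 1654 lower, and the dye-corrected ratios of 3155 of the 3268 had 1 sign on every array. The dye term was estimated from these same arrays and brings the 2 orientations closer, so this count can overstate their agreement. Before the term, arrays of 1 orientation correlated across genes at 0.625 and 0.795, and arrays of opposite orientation at 0.15 to 0.528. The dyes were balanced here, and 1262 higher and 1379 lower genes passed without the dye term too. The count was 3898 within slide 3 and 2799 within slide 4, and 842 with a spread estimated from the prepupae arrays alone. In the authors' value table, which pairs the columns of 1 prepupae array with the other genotype, 22 genes passed, and Hsp70Bb, Hsp70Ba and Hsp26 stood at -1.30, -0.61 and -0.06.

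Heat shock genes rose in 13 of 18 cases in prepupae (13 adjusted over the list alone), among them Hsp23 at 2.11 ± 0.10 and Hsp67Bc at 2.42 ± 0.18. Their median was 2.27 (camera adjusted p = 1.65e-07; adjusted p = 0.896 with an estimated correlation), with 2.68 and 1.65 on the arrays of slide 4 and 2.32 and 2.80 on those of slide 3. The 71E late puff genes, which the ecdysone cascade turns on at the end of larval life, fell in 10 of 10 cases (10 adjusted over the list alone). Eig71Ea fell to -1.57 ± 0.08, Eig71Eb to -2.25 and Eig71Ec to -1.98, and the median was -1.62 (camera adjusted p = 2.69e-05; adjusted p = 0.896 with an estimated correlation), with -1.68 and -1.13 on slide 4 and -1.29 and -3.05 on slide 3. Muscle structural genes fell in 23 of 26 cases (23 adjusted over the list alone), including TpnC41C, a troponin C gene, at -3.17 ± 0.24 and the muscle LIM protein gene Mlp60A at -1.70 ± 0.14. Their median was -1.62 (camera adjusted p = 8.74e-11; adjusted p = 0.896 with an estimated correlation), with -2.81 on slide 4 and -2.03 on slide 3 on the arrays with RNAi in Cy5, and -1.12 on slide 4 and -0.15 on slide 3 on those with RNAi in Cy3.

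Mitochondrial ribosomal protein genes fell in 47 of 64 cases in prepupae (50 fell and 1 rose adjusted over the list alone), with mRpS35 at -1.33 and mRpL27 at -0.96 (median -0.41, camera adjusted p = 4.33e-10, adjusted p = 0.896 with an estimated correlation). Midgut digestive enzyme genes fell in 7 of 8 cases (8 adjusted over the list alone), with the serine protease genes Jon99Fii at -4.44 ± 0.45 and Jon65Ai at -3.72 ± 0.39 (median -2.65, camera adjusted p = 4.62e-05, adjusted p = 0.896 with an estimated correlation). Glutathione S-transferase genes rose in 14 and fell in 4 of 23 cases (the same counts adjusted over the list alone), with GstE1 at 2.50, GstE7 at 2.33 and GstE3 at 2.09 (median 0.70, camera adjusted p = 0.0072, adjusted p = 0.896 with an estimated correlation). Mitotic genes rose in 7 of 21 cases (7 adjusted over the list alone), including the cytokinesis genes tum at 1.04 and pav at 0.65 (median 0.21, camera adjusted p = 0.0226, adjusted p = 0.896 with an estimated correlation). Proteasome subunit genes fell in 15 and rose in 1 of 32 cases (the same counts adjusted over the list alone), with Rpt5 at -0.62 and Rpn8 at -0.55 (median -0.28, camera adjusted p = 0.0334, adjusted p = 0.896 with an estimated correlation). Median centring in place of loess moved the median of all tested genes to -0.41, and the share of higher genes among those called from 49.4% to 12.6%; no list above turned direction with it.

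**Figure D3:**
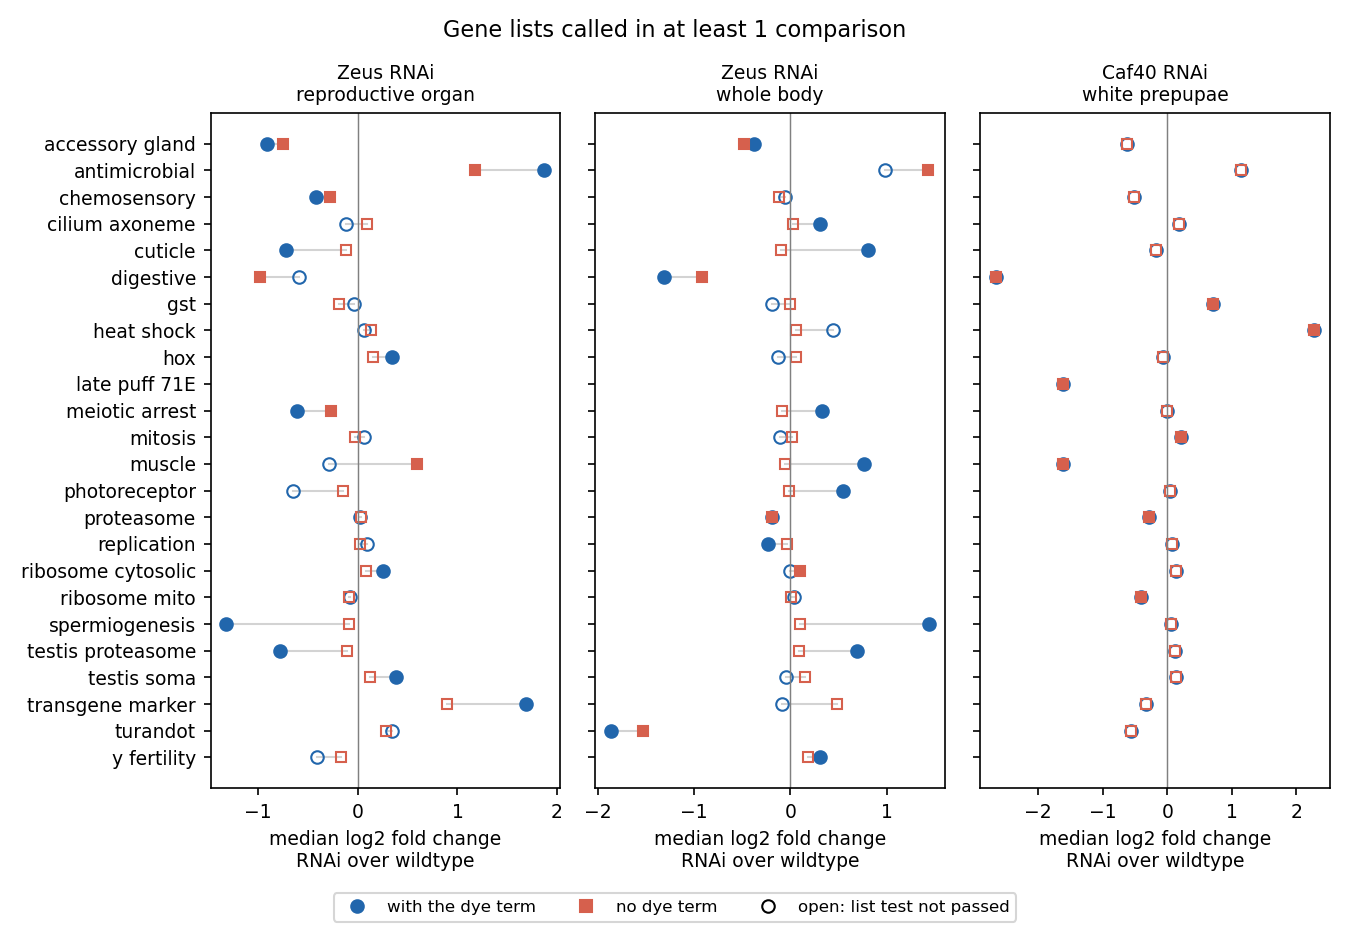
Median log2 ratio of RNAi over wildtype of each gene list called in at least 1 comparison, in reproductive organ, whole body and prepupae, as circles with the dye term and squares without it, open where the list test was not passed. The spermatid list moved from -1.32 to -0.09 in reproductive organ and from 1.44 to 0.11 in whole body when the term was left out, and heat shock genes stood at 2.27 in prepupae in both fits.

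The difference between the response to Zeus RNAi in reproductive organ and in whole body was tested directly. With the dye term, CG7365 (3.60 ± 0.38), the chitinase-like gene Cht9 (3.51 ± 0.72) and Ag5r (3.14 ± 0.35) had the highest differences, and Osi12 (-5.76 ± 0.55), CG31626 (-5.52 ± 0.38) and the cuticle protein gene Cpr66Cb (-5.24 ± 1.08) the lowest. Without the term the same genes stood at 0.82, 1.68, 1.12, -0.59, 0.04 and 0.12, and none passed. Of 11304 genes, 371 were higher and 965 lower in reproductive organ than in whole body with the term, and 2 were lower without it. These 2, named after their values were seen, were CG15772 at -1.51 and CG17572 at -1.49. Fitted to the Zeus arrays and the technical array with a dye term of their own, limma called 0 genes at the adjusted threshold and 965 at an unadjusted p under 0.05. With the prepupae dye term the count was 64 and 812 without reproductive organ replicate 1 or 2, 6, 5 and 70 without whole body replicate 1, 2 or 3, and 3079 and 797 without prepupae replicate 3 or 4.

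Across the same 11304 genes, the log2 ratios of the 2 Zeus comparisons correlated at r = -0.144 (Spearman rho = -0.213) with the dye term and at 0.698 (0.488) without it. With the term, r was -0.366 without prepupae replicate 3 and -0.0127 without prepupae replicate 4. The dye term is shared by both with opposite sign, and unchanged simulated comparisons gave r = -0.426 with it and a covariance of -0.04, against -0.07 observed. Without the term the covariance was 0.18 against -1.94e-05 simulated, a value near 0 that independent noise on every array builds in. Without the term 159 genes were higher in both, where independent lists would share 14, and 225 were lower in both, where independent lists would share 17.8, and no gene was called in opposite directions. Male whole body includes the reproductive organ, so genes shared by both need not have responded in other tissues. With the term 111 were higher in both (independent lists, 79.5), 159 lower in both (67.2) and 367 lower in reproductive organ and higher in whole body (91.8). Genes lower in both fits and both sample types included Cyp12d1-d, thetaTry and the cytochrome P450 gene Cyp4p2 (-2.35 ± 0.20 and -1.93 ± 0.20), and Socs36E, an inhibitor of JAK/STAT signalling, was higher in both (2.32 ± 0.17 and 0.73 ± 0.17).

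The young gene and its parent were compared through Zeus RNAi in reproductive organ minus Caf40 RNAi in prepupae, where gene and sample type change together. Slides, scan and Feature Extraction version change along with them. Act88F was higher in the Zeus comparison by 4.50 ± 0.55 on the log2 scale (5.12 without the dye term), CG10912 by 6.54 ± 0.73 and CG7924 by 6.32 ± 0.46. Tep2 was lower by a difference of -5.44 ± 0.45, Hsp68 of -5.01 ± 0.47 and CG4998 of -7.55 ± 1.23. The values of these genes and of CG10912 and CG7924 carry the dye term, without which the fall of CG4998 in reproductive organ did not pass. Of 7805 genes, 880 were higher and 968 lower with the dye term, and 876 and 533 without it, with 658 and 362 in both. The count was 602 without prepupae replicate 4, 3160 without prepupae replicate 3, 651 and 1047 without reproductive organ replicate 1 or 2, and 998, 1012 and 1070 without whole body replicate 1, 2 or 3. Across genes the 2 responses correlated at r = 0.218 (rho = 0.222) with the term and at 0.177 (0.147) without it. Unchanged simulated comparisons gave 0.00122 with the term. Their noise was independent on every array, so a value near 0 was built in and leaves out effects that arrays share. The measured correlation was -0.0758 without prepupae replicate 3 and 0.381 without prepupae replicate 4, and it turned negative with scaling between arrays. With the term 439 genes were higher in both, where independent lists would share 195, and 187 were lower in both, where they would share 192. In opposite directions, 84 were higher under Zeus RNAi and lower under Caf40 RNAi (independent lists, 193) and 39 the other way round (194). Without it 179 were higher in both (independent lists, 93.1) and 97 lower in both (45.1), and 83 (97.9) and 39 (42.9) went in opposite directions.

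Caf40 is X-linked and Zeus is not, and the share of changed genes on the X was compared with that of the other tested genes. Genes higher under Zeus RNAi in reproductive organ lay on the X in 20.9% of cases, against 15.9% of tested genes (odds ratio 1.46, two-sided Fisher's exact test, adjusted p = 3.3e-06 over 6 tests; 1.27 and 0.0296 without the dye term). Genes lower there lay on the X in 14% (odds ratio 0.839, adjusted p = 0.0364), which did not pass without the term (adjusted p = 0.0547). Genes higher under Caf40 RNAi lay on the X in 18.4%, against 15.8% of tested genes (odds ratio 1.26, adjusted p = 0.00522), and genes lower in 13.8% (odds ratio 0.816, adjusted p = 0.02). In whole body the odds ratio of higher genes was 0.782 (adjusted p = 0.0364) with the dye term and 1.34 (adjusted p = 0.112) without it, and that of lower genes was 1.11 (adjusted p = 0.37). The call of lower genes in reproductive organ was lost without any 1 of its own arrays (0.975, 0.897 and 0.954 for replicates 1 to 3) or of the whole body arrays (0.836, 0.834 and 0.84). The whole body call of higher genes was lost without reproductive organ replicate 1, 2 or 3 (0.955, 1.05 and 0.966), whole body replicate 1, 2 or 3 (1.31, 1.56 and 1.07) or prepupae replicate 1, 2 or 4 (0.891, 0.927 and 0.859). Lower genes in whole body passed without reproductive organ replicate 2 (1.40), whole body replicate 1 or 3 (1.79 and 1.78) or prepupae replicate 2 (1.28). The prepupae call of higher genes was lost without replicate 2 or 3 (1.14 and 1.09) and that of lower genes without replicate 3 (0.855). Genes are not independent samples in these tests.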

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

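The tests of explanations in this part were chosen after the results were seen, except the test on missing green signal and the counts over other splits of the samples, whose limit to splits that keep the samples of an array apart was set afterwards. Genes differing between reproductive organ and whole body under Zeus RNAi stood out because the difference itself passed a test, 1336 in all. The highest were CG7365 at 3.60, Cht9 at 3.51, Ag5r at 3.14, CG7079 at 2.80, CG9673 at 2.76 and Cyp4e3 at 2.74, and the lowest Osi12 at -5.76, CG31626 at -5.52, Cpr66Cb at -5.24, Osi2 at -5.22, Twdlbeta at -5.12 and CG12860 at -4.91.

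A difference between the sample types as the cause of this whole set is argued against by the fit of the Zeus arrays with their own dye term, in which 62 of the 1336 genes (4.64%) kept at least 0.5 times their difference. Genes that lacked a green spot well above background on at least 1 prepupae array were counted as missing green signal. Missing green signal is argued against as well, with 546 of the 1336 genes (40.9%), against 4732 of 9968 other genes (47.5%, odds ratio 0.765, Fisher's exact test, p = 5.9e-06). The test used this mark alone and not the signal level, so it cannot speak on other faults of the green channel. A candidate explanation is that the dye effects of the prepupae arrays do not carry over to the Zeus arrays, because the dye effect within reproductive organ correlated with the prepupae dye term at 0.0886, where simulations of a term present on all arrays gave 0.834 to 0.862 and of one on the prepupae arrays only -0.0367 to 0.0453. Whole body has no technical array and allowed no such check. The technical array also differed from the biological ones in slide and scan, which the simulations did not hold. With dye terms on the prepupae arrays alone and no changed gene, simulated data gave 1900 such genes on average (1769 to 2015), against 1336 found. The estimated terms hold noise of their own and were not scaled for it here, so the simulated counts can run high.

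The shift shared by reproductive organ and whole body without the dye term, r = 0.698 across genes, came from arrays of opposite dye orientation, and a dye bias would give a correlation below 0. A background difference in 1 chromosome arm is argued against, since the arm with the highest odds ratio among the genes shared in 1 direction, the X, stood at 1.33 (76 of 382 genes, Fisher's exact test, adjusted p = 0.197). A strain difference common to all 3 comparisons stays open, since whole body and prepupae correlated at 0.279 across genes, and at 0.257 to 0.292 when 1 array was left out, below 0.698 but above 0. A strain difference that acts in adult males alone and an effect of Zeus RNAi itself stay open too, and these data do not part them. Whole body includes the reproductive organ, so a change in that organ alone could also appear in both, which was not tested.

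Under Caf40 RNAi, heat shock genes were higher and 71E late puff genes lower with medians of at least 0.5 in size on 4 of 4 arrays, which argues against 1 array or 1 dye orientation as their source. For muscle genes the medians were uneven, -2.81 and -2.03 with RNAi in Cy5 and -1.12 and -0.15 with RNAi in Cy3, for which the cause was not tested. A dye bias, which cancels over the 2 orientations, is argued against as the source of the fall by the median of -1.62 over both with 23 of 26 genes lower, and 1 array alone by medians of -1.75 to -1.25 when any 1 was left out. A mislabelled array, as the genotypes turned in the authors' value table would have it, is argued against by the responding Caf40 probe, which stood at -3.44 on that array under the labels used here. A difference in developmental stage at collection and an effect of Caf40 RNAi on development both stay open, since that 100% of the tested 71E late puff genes (10 of 10) moved in 1 direction is the pattern itself and parts neither.

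The digestive enzyme list stood at a median of -4.31 on prepupae replicate 4, away from -2.11 to -1.69 on the other 3 arrays. The green median background of prepupae replicate 3 was 24, against 27 on each of the other 3. Such gaps were sought in 64 named genes, 8 array measures and 8 lists, and arise in about 1 of 20 groups by chance. The technical array, left out of the fit with all comparisons, showed Zeus at -2.17.

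Counts of changed genes were repeated over other splits of the samples. The RNAi and wildtype samples of a comparison share arrays, so only splits that keep the samples of every array apart were counted. In prepupae the real split gave 3020 genes in the separate-channel fit and the highest other, which turned replicate 3, gave 1715, with 7 splits, so that no share can be under 0.143. In reproductive organ the real split gave 2509 genes and the highest other 1, and in whole body 1205 and 0, with 4 splits each and no share under 0.25. For the difference between them these were 1336 and 0, with 10 splits and no share under 0.1. The real splits of these 3 Zeus results were also those of the dyes. For reproductive organ minus prepupae chance was not excluded, as 2 of 35 splits gave as many, the real one 1848 and another 1939. That other split set prepupae replicates 1, 2 and 4 against replicate 3 and the reproductive organ arrays, while the real one also followed the slides.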

How the results depend on the processing

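The fit without the dye term and with the technical array together, both fits of the Zeus arrays alone, the fit with unannotated transcripts and that with prepupae replicate 4 turned were chosen after seeing the data. A separate fit of a Zeus comparison also lacks the dye term. Where a value moved and no construction of the setting explains it, the cause was not tested. Of 184 named genes, 145 kept direction and threshold without the dye term, 149 with slide as a random block, 139 with the stricter filter, 49 in the value table, 47 with prepupae replicate 4 turned, and all 184 with no filter on dim probes or with an intensity trend. In prepupae 8020 genes were tested, against 11350 in reproductive organ and 12008 in whole body. How far the low share of green spots well above background on the prepupae arrays accounts for this was not tested.

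Genes changed in reproductive organ numbered 2809, and 1398 without the dye term, 1206 fitted alone, 1650 with slide as a random block, 1709 with array weights, 481 in the value table, 1446 at 2-fold or more, 535 and 1137 within slides 1 and 2, and 500 with prepupae replicate 4 turned. The Zeus arrays with their own dye term gave 3089 such genes, and the Zeus biological arrays alone, without a dye term, gave 3919. With 1 array left out of the main fit, changed genes ranged from 1137 (without reproductive organ replicate 1) to 3922 (without prepupae replicate 3). In whole body they numbered 1259, and 572 without the dye term, 412 with the technical array, 701 with both changes, 4304 fitted alone, 2579 with processed signals, 2976 without background correction, 2262 with scaling, 177 with slide as a block, 60 in the value table, 2346 at an adjusted p of 0.1, 794 at 2-fold, 822 with the Zeus arrays' own dye term, 2179 in the Zeus biological arrays alone and 55 with replicate 4 turned, and 120 to 3401 with 1 array left out. In prepupae they numbered 3268, and 842 fitted alone, 2090 with scaling, 1458 with weights, 22 in the value table, 1020 at 2-fold and 7 with replicate 4 turned (770 at an unadjusted p under 0.05), and 2539 to 3954 with 1 array left out.

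Genes differing between reproductive organ and whole body numbered 1336, and 2 without the dye term, 0 with the technical array (1147 at an unadjusted p under 0.05, limma), 5 with both changes, 0 with the Zeus arrays' own dye term (965), 0 with replicate 4 turned (1575), 274 fitted alone or in the Zeus biological arrays alone, 2949 with processed signals, 3099 without background correction, 3 with slide as a block, 1 in the value table and 2427 at an adjusted p of 0.1, and 5 (without whole body replicate 2) to 3079 (without prepupae replicate 3). Those between reproductive organ and prepupae numbered 1848, and 341 fitted alone, 2939 with processed signals, 3210 without background correction, 3036 with median centring, 539 with weights, 4 in the value table, 2910 at an adjusted p of 0.1, 1223 at 2-fold and 1 with replicate 4 turned, and 602 to 3160.

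The replicate block, the pairing of samples on an array, was taken out in a separate-channel fit. With no replicate block 2509, 1205 and 3020 genes were called in the 3 comparisons and 1210 and 1786 in the 2 differences, all within 1.5 times the paired counts. Not every array's pairing exceeded a correlation of 0.1. Without the block, Caf40 in whole body passed (-0.85, adjusted p = 0.0377), and the X odds ratios of genes higher in whole body (0.815) and in prepupae (1.14) no longer passed.

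The correlation of reproductive organ with whole body was -0.144, and turned to 0.698 without the dye term, fitted alone or in the Zeus biological arrays alone, 0.434 with the technical array, 0.733 with both changes, 0.709 with the Zeus arrays' own dye term and 0.0852 with scaling. It was -0.263 with processed signals, -0.31 without background correction, -0.309 with median centring, -0.0321 in the value table and -0.017 with replicate 4 turned, and -0.366 to -0.0127 with 1 array left out. That of reproductive organ with prepupae, 0.218, turned to -0.264 with scaling, and ran from -0.0758 to 0.381.

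Zeus kept its direction in each setting run. In reproductive organ it did not pass within slide 1 (-2.04), and ranged from -2.51 to -1.93 with 1 array left out. In whole body it did not pass with processed signals (-2.07), slide as a block (-1.32) or replicate 4 turned (-1.53), with a range of -1.66 to -1.08, and in prepupae the range was -0.71 to -0.13. Caf40 in reproductive organ did not pass with scaling (-0.59), no filter (-0.84), slide as a block (-0.85), the value table (-0.58), 2-fold (-0.84), within slides 1 (-0.93) and 2 (-0.80) or with replicate 4 turned (-0.58), and ranged from -1.15 to -0.54. In whole body it passed without the dye term, with that and the technical array, fitted alone and in the Zeus biological arrays alone (-0.90 each), with their own dye term (-0.92), processed signals (-1.36), no background correction (-1.22), median centring (-0.98), scaling (-1.46), weights (-0.85) and an adjusted p of 0.1 (-0.85), and ranged from -1.16 to -0.55. In prepupae it was not tested with the stricter filter (-1.39) and did not pass in the value table (-0.52) or with replicate 4 turned (-0.52), with a range of -1.69 to -1.08.

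The X odds ratio of genes higher in reproductive organ (1.46) did not pass with replicate 4 turned (1.68), with a range of 1.33 to 1.76 over arrays left out. That of genes lower there (0.839) did not pass without the dye term (0.775), with the technical array (0.913), both (0.843) or no filter (0.856), and turned with median centring (1) and replicate 4 turned (1.08), with a range of 0.78 to 0.975. For genes higher in whole body (0.782) it turned without the dye term (1.34), with the technical array (1.83), both (1.32) and replicate 4 turned (1.31), and did not pass with median centring (0.874), no filter (0.87) or the brightest probe (0.823), with a range of 0.799 to 1.56. For genes lower there (1.11) it passed with the technical array (1.39), with a range of 1.05 to 1.79. In prepupae it did not pass with median centring for higher (1.11) and lower genes (0.884), nor for lower genes with the stricter filter (0.844), and both were 0 with replicate 4 turned, with ranges of 1.09 to 1.32 and 0.785 to 0.855.

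Of 120 gene list results camera called 32, and 0 with an estimated correlation. Fry called 26, of which 15 were among the 32, and camera called 24 to 34 with 1 array left out. Without the dye term, and also with the technical array added, meiotic arrest (-0.0864), muscle (-0.0591) and cuticle genes (-0.0942) turned in whole body, and accessory gland genes did with median centring (0.00711). Of the single genes, CG31626 turned in the difference between the Zeus comparisons (0.0353 without the dye term, fitted alone or in the Zeus biological arrays alone, 0.0731 without the term and with the technical array, and 0.186 with their own dye term), as did Cpr66Cb (0.123) and, with their own dye term, Twdlbeta (0.0157). CG31704 in whole body turned without the dye term, also with the technical array, fitted alone and in the Zeus biological arrays alone (-0.0435 each), and with their own dye term (-0.108). Not11 turned with the brightest probe in reproductive organ (-0.156) and prepupae (-0.0963). In the value table ImpL2 turned in reproductive organ (-0.113), and Hsp70Bb (-1.30), Hsp70Ba (-0.609) and Hsp26 (-0.0566) turned in prepupae.

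Processed signals moved the median of all genes to 0.18 in reproductive organ and -0.16 in whole body, and median centring to -0.11 in whole body. Higher genes made up 46.3% of those called in reproductive organ, 56.7% with processed signals, 36% with median centring and 33.1% in the value table. In whole body they made up 56.6%, and 38.3% without the dye term and 30% in the value table. Slides had a consensus correlation of 0.316, and array weights ran from 0.281 to 4.86.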

Other observations

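The genes and lists in this part were chosen after their values were seen, except where a list was fixed in advance. Several genes passed in all 3 comparisons in 1 direction with the dye term. ImpL2, which encodes a secreted antagonist of insulin signalling, stood at log2 1.01 ± 0.28 in reproductive organ, 1.20 ± 0.28 in whole body and 2.56 ± 0.18 in prepupae, and passed in all 3 without the term. BaraA2 stood at 3.92 ± 0.47, 1.89 ± 0.47 and 4.33 ± 0.31, and Socs36E at 2.32 ± 0.17, 0.73 ± 0.17 and 1.45 ± 0.11, both passing in the 3 comparisons without the term as well. CG34331 was at least 9.75-fold, 24.3-fold and 7.79-fold higher in the 3. Cyp12d1-d, lower under Zeus RNAi in both sample types, was higher under Caf40 RNAi, at 0.92 ± 0.22 (adjusted p = 0.0103). Whether more genes were shared by the 3 comparisons than chance gives was not tested.

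Of 7 other members of the CCR4-NOT complex tested in prepupae 3 passed, against 3268 of all 8020 genes. Under Caf40 RNAi, Not3 fell to -0.70 ± 0.09 and Rga to -0.73 ± 0.14, and Not11 rose to 0.34 ± 0.10. Under Zeus RNAi in reproductive organ 3 of 8 passed, Not10 at 0.97 ± 0.19, Not11 at 0.51 ± 0.15 and twin at -0.73 ± 0.19, and without the dye term these stood at 0.82, 0.07 and -0.09 and Not10 alone passed. With the brightest probe of each gene Not11 turned in both comparisons (-0.156 in reproductive organ and -0.0963 in prepupae). The fat body proteins Fbp1 and Fbp2 fell in prepupae to -2.82 ± 0.21 and -2.16 ± 0.13, while the lipase gene bmm rose to 1.65 ± 0.17 and the storage protein gene Lsp1beta to 2.66 ± 0.41. Among ecdysone response genes 5 rose and 10 fell of 20, with E23, an ecdysone-inducible transporter gene, at -1.62 ± 0.15. Neither list passed by camera (fat body adjusted p = 0.0785, ecdysone response 0.264), while by fry the fat body list passed (adjusted p = 0.00265) and the ecdysone response list did not (0.0998). The eye colour gene w, a marker carried by many transgenes, rose under Caf40 RNAi to 3.76 ± 0.32, or 13.5-fold, with ratios between 1.59 and 5.12 on the 4 arrays. Another eye colour marker, v, fell to -1.04 ± 0.32 (adjusted p = 0.0305; 0.0959 without the dye term), a call lost without replicate 1, 2 or 4 (-1.02, -1.05 and -0.73). Under Zeus RNAi in reproductive organ the transgene marker list was called higher, with 3 of 3 members (3 adjusted over the list alone; median 1.69, camera adjusted p = 0.0338, adjusted p = 0.896 with an estimated correlation). There w stood at 1.69 ± 0.48, v at 2.15 ± 0.49 and ry at 1.13 ± 0.22, and without the dye term at 0.67, 1.24 and 0.90 with ry alone past the threshold. The list was not called without the term (median 0.90, adjusted p = 0.121). The call of w was lost without any 1 reproductive organ array (1.61, 1.55 and 1.92), any 1 whole body array (1.69 each) or prepupae replicate 1 (1.52), and that of v without reproductive organ replicate 1 or 2 (1.67 and 2.08). In whole body w stood at 0.53 with the term (adjusted p = 0.501) and 1.56 without it (adjusted p = 0.155). The splicing factor gene tra of the sex determination pathway rose to 1.62 ± 0.09, and the male-specific lncRNA:roX2 fell to -1.07 ± 0.21, in samples whose sex is not given.

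Prepupae replicate 4 went against the other 3 arrays in several lists. The median ratio of salivary glue genes was 2.50, 3.11 and 0.62 on replicates 1 to 3 and -4.48 on replicate 4. That of antimicrobial genes was 3.59, 1.22 and 2.36 against -2.16, and that of cuticle protein genes -0.63, -1.54 and -0.35 against 1.69. Heat shock genes stood at 2.80 on replicate 4 and 71E late puff genes at -3.05, on the same side as on the other arrays.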
